A study of Mus musculus with 4 samples.

How the data were processed

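Small RNA was sequenced from 2 mouse mammary carcinoma lines, 4T1 and 4TO7, and from the extracellular vesicles (EVs) that each line released, which gave 4 libraries with 1 library per group. Per the labels' protocols, the cells were grown in DMEM with serum from which EVs had been removed. EVs were collected by differential centrifugation with rounds of ultracentrifugation, RNA was extracted with Trizol, and ribosomal RNA was depleted with a Ribozero kit. RNA of miRNA size was excised from a denaturing gel, and libraries were made with a NEBNext small RNA kit. Per the labels, the 4 libraries carried separate index primers and shared a sequencing lane.

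Per the submitters' processing notes, the tools were cutadapt, Bowtie and bedtools and the genome build was mm9, with no versions given. The alignment logs that the authors deposited show 2 Bowtie runs per library, each allowing 1 mismatch over the whole read. The run against mm9 reported up to 6 positions per read, and the run against mature mouse miRNAs reported up to 10 matches per read. A read was therefore listed under each mature miRNA that it matched, up to that limit, and 1 read of 18 nt or more gave between 1.37 and 1.60 alignments. Members of families such as let-7, miR-27 or miR-10 shared reads in this way, so the values of near-identical miRNAs are not independent. Reads that ran past the annotated 3' end of a mature miRNA could not align over their whole length in the second run.

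Each library had a table of read lengths, an alignment log, a miRNA table and a table of genome clusters. The miRNA tables deposited by the authors hold raw counts of alignments per miRNA, strand, start position and length, from 10 nt upwards. The cluster tables deposited by the authors hold counts of alignments per region of mm9, and no listed cluster had a total below 1300. In the 4T1 EV table the authors also deposited a per-read-total column, whose values were RPM of all reads of that library. It was filled in 1030 lines, all of which equalled the count divided by the library's reads within a relative tolerance of 1e-06, and the shortest length it covered was 18 nt. Reads of 9 nt had no entry in the miRNA rows of the length tables and were not used here.

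From these files, alignments on the sense strand with a length of 18 nt or more were summed per mature miRNA. The 18 nt minimum was taken from the authors' RPM column after the files were seen, and other minimums were tried. The totals, which served as library sizes, were 57962 in 4T1 EV, 51697 in 4TO7 EV, 603186 in 4T1 cells and 177647 in 4TO7 cells. A miRNA with 0 reads is thereby limited to 3 reads of the total, which is 51.8 RPM in 4T1 EV, 58.0 in 4TO7 EV, 4.97 in 4T1 cells and 16.9 in 4TO7 cells.

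The design gives 4 comparisons, which are EVs against cells in each line, and 4T1 against 4TO7 in cells and in EVs. Each used the ratio of RPM of miRNA-assigned reads. Log2 ratios had 0.5 reads added to each count. The exact conditional binomial (Clopper-Pearson) 95% interval of the ratio was computed for every mature miRNA with 50 or more reads in at least 1 of the 2 libraries. A miRNA was called higher when the interval lay wholly above 2-fold and lower when it lay wholly below a ratio of 0.5. With 1 library per group no variance between replicates can be estimated. The calls therefore compare libraries and not conditions, no p-value is given across miRNAs, and all intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Where 1 library had 0 reads, the fold is given as a lower bound against a floor of 3 counts in that library. This bound leaves out the counting error of the other library, so the exact interval can start below it. For miR-200c-3p between cells the interval starts at 95.8 and the bound is 118.

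The 21 miRNA lists were fixed before the data were examined, as were the rule for calls, the minimum of 50 reads and the rule for naming miRNAs. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 10 bins of mean abundance, for lists with at least 3 compared members. This percentile describes these libraries. The rule named, in each comparison, the 10 called miRNAs with the largest and the 10 with the smallest log2 ratio, the 10 most abundant miRNAs of each library, and up to 4 members of each list with the most reads. The difference between the EV/cell log2 ratios of the lines had an interval from summed Poisson variances. Shares of reads have exact Clopper-Pearson 95% intervals.

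On simulated Poisson counts drawn from the real abundances and library sizes, none of the unchanged miRNAs was called in any comparison. These counts held no spread between cultures or preparations, so they cannot show how often such spread would give a call. For 4T1 EV against cells, the calls recovered 60.0% of 25 tested miRNAs changed 4-fold and 88.5% of 26 changed 8-fold. For 4TO7 EV against cells they recovered 90.9% of 22 changed 4-fold, for the cells 90.9% of 33, and for the EVs 95.0% of 20. The intervals held the true ratio for 91.2% to 96.9% of simulated miRNAs per comparison.

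Alternatives were TMM scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, all genome-aligned reads as the denominator, minimums of 10 and 200 reads, 5 reads added, the most abundant miRNAs left out of the denominator, thinning to the shallower library and summing of both arms of a hairpin. Minimum lengths of 16 and 21 nt, minimums of 10 to 17 nt for the miRNAs lower in both EV libraries, all listed lengths with both strands, collapsed letter-suffix paralogs and clusters of 10000 or more alignments were chosen after seeing the data, as were median-of-ratios and genome-aligned scaling of the EV/cell difference and all settings for the miRNAs called in both lines. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Cluster positions are printed as listed, on mm9, with the labels the authors typed beside some clusters, which could not be checked. Genome positions of single mature miRNAs were not used here, because the available reference was on another build.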

Results

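4T1 and 4TO7 are related mouse mammary carcinoma lines derived from the same parental tumour. 4T1 cells spread and grow in distant organs, whereas 4TO7 cells are known for poor growth at distant sites. The series compared small RNA of cells and of the EVs they released, which are membrane-bound particles that carry RNA out of cells. There was 1 library for each of the 4 groups, so there was no replicate error and every interval below covers counting error only. The libraries held 9729966 reads in 4T1 EV, 7111921 in 4TO7 EV, 16220214 in 4T1 cells and 13865266 in 4TO7 cells. Of the reads processed by the aligner, 78.4%, 72.7%, 86.4% and 82.1% aligned to the genome in the same order.

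Reads that aligned to mature miRNAs made up a small part of each library, and a smaller part in EVs than in cells. Reads past the annotated 3' end of a mature miRNA could not align and are missing from these shares. At any read length, the genome cluster labelled mir-21 alone held alignments equal to 4.45% of genome-aligned reads in 4T1 cells and 1.55% in 4TO7 cells. The same cluster held 0.0443% in 4T1 EV and 0.0971% in 4TO7 EV. Reads of 18 nt or more that aligned to mature miRNAs were 0.574% of genome-aligned reads in 4T1 EV (95% interval 0.569% to 0.580%) and 0.630% in 4TO7 EV (0.623% to 0.637%). The corresponding shares were 3.11% in 4T1 cells (3.10% to 3.12%) and 1.09% in 4TO7 cells (1.08% to 1.09%). In all, 311 mature miRNAs had at least 1 such sense read in 4T1 EV, 323 in 4TO7 EV, 560 in 4T1 cells and 441 in 4TO7 cells. The numbers of miRNAs depend on depth, which was lower in the EV libraries. The 10 most abundant miRNAs took 56.1% of miRNA reads in 4T1 EV, led by miR-5099 and miR-125b-5p, and 59.6% in 4TO7 EV, led by let-7a-5p and let-7c-5p. They took 54.2% in 4T1 cells, led by miR-21a-5p and let-7j, and 55.0% in 4TO7 cells, led by miR-21a-5p and let-7a-5p.

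The small RNAs of EVs had sharp length peaks. The most common length was 24 nt in 4T1 EV, with 16.1% of reads, and 30 nt in 4TO7 EV, also with 16.1%. The 30 nt length was the second peak of 4T1 EV, at 14.3%. In 4T1 cells the most common length was 23 nt with 8.32% of reads, and in 4TO7 cells it was 27 nt with 7.90%. Reads of 20 to 24 nt were 46.3% of 4T1 EV, 35.7% of 4TO7 EV, 24.2% of 4T1 cells and 19.7% of 4TO7 cells. Among miRNA reads of 18 nt or more, 22 nt was the most common length in cells, with 60.6% in 4T1 and 64.0% in 4TO7. The 21 to 23 nt window held 18.03% of all reads in 4T1 EV, 20.9% in 4TO7 EV, 17.3% in 4T1 cells and 13.7% in 4TO7 cells. The difference between EVs and cells was thus smaller in that window for 4T1 and remained for 4TO7. In EVs 22 nt took 27.6% in 4T1 and 45.6% in 4TO7. Reads of 18 nt, the shortest counted, were 31.3% of these miRNA reads in 4T1 EV (30.9% to 31.8%) and 18.5% in 4TO7 EV (18.03% to 18.9%), against 0.912% in 4T1 cells and 1.09% in 4TO7 cells.

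**Figure D1:**
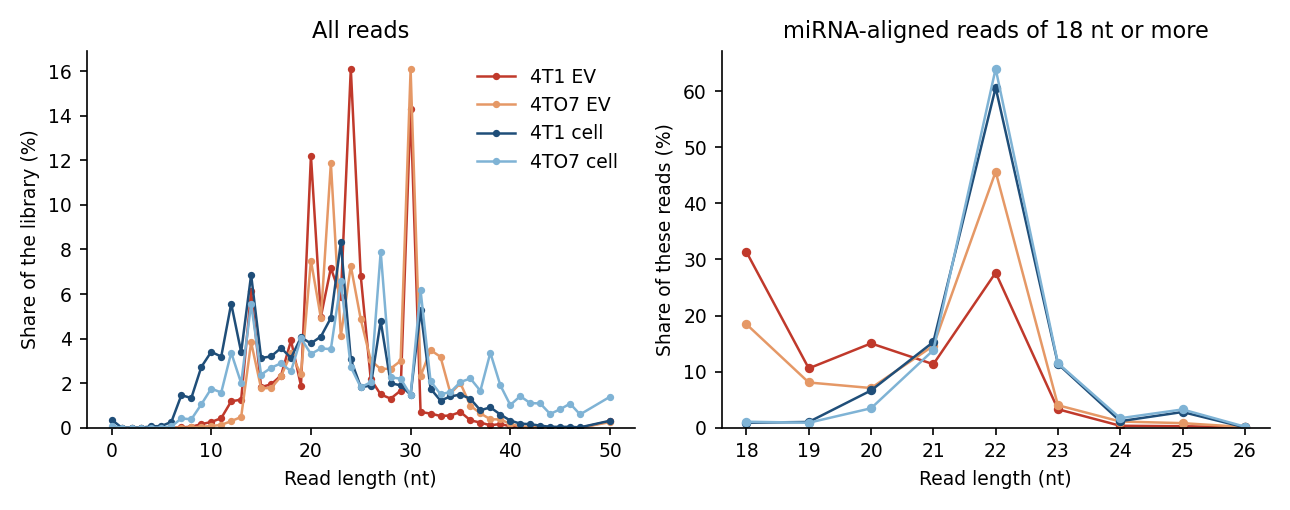
Read lengths in the 4 libraries, 1 library per group, as the share of all reads (left) and of miRNA-aligned reads of 18 nt or more (right), in percent against length in nt. Each point is 1 length in 1 library; over all reads 4T1 EV peaks at 24 nt and 4TO7 EV at 30 nt, and 31.3% and 18.5% of their miRNA reads are 18 nt long.

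Outside miRNAs, the largest clusters of the EV libraries carried labels of U2 snRNA, an RNA component of the spliceosome, whereas labels of ribosomal RNA stood among the largest clusters of the cell libraries. A cluster that the authors labelled U2 snRNA (mm9, chromosome 8, 53422336 to 53422386) held alignments equal to 33.8% of genome-aligned reads in 4T1 EV and 20.1% in 4TO7 EV. It was not listed in either cell library. A second U2 copy (chromosome 11, 101466254 to 101466329) held 30.0% and 19.3% in EVs against 0.0108% in 4T1 cells and 0.0134% in 4TO7 cells. Clusters were listed separately in each library, and this one covered 75 nt in 4T1 EV, 50 nt in 4TO7 EV and 25 nt in both cell libraries. Because a read could be reported at up to 6 positions, clusters of copies of the same RNA share reads and their shares cannot be added. A cluster labelled snRNA (chromosome 1, 72301672 to 72301747) held 23.01% and 12.1% in EVs and was not listed in cells. The 10 largest clusters of 4T1 EV all overlapped the 10 largest of 4TO7 EV, and none overlapped the 10 largest of either cell library.

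In cells, the largest cluster lay on chromosome 17 (39984151 to 39985051 in 4T1 cells, labelled Erf1 by the authors), with 14.5% of genome-aligned reads in 4T1 cells. That label was not checked, and which RNA these reads came from was not tested. In 4TO7 cells the region was listed as 2 clusters, with 12.0% (39984431 to 39985056) and 9.34% (39984131 to 39984406). The EV libraries each listed 4 overlapping clusters, the largest with 1.10% in 4T1 EV and 1.30% in 4TO7 EV. A cluster labelled as small-subunit rRNA (chromosome 6, 3151501 to 3151576) held 6.28% in 4T1 cells and its overlapping cluster 10.3% in 4TO7 cells. The value in 4T1 EV was 0.237%, and no overlapping cluster was listed in 4TO7 EV. A cluster labelled ERVL, an endogenous retrovirus class (chromosome 10, 82418151 to 82418201), held 4.83% in 4T1 cells, 6.41% in 4TO7 cells and 0.0754% in 4T1 EV, with no overlapping cluster listed in 4TO7 EV. In total 684 clusters were listed in 4T1 EV, 465 in 4TO7 EV, 1877 in 4T1 cells and 1171 in 4TO7 cells, and these numbers depend on depth.

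The comparison of 4T1 EVs with 4T1 cells asked which miRNAs were over- or under-represented in vesicles relative to their cells of origin. Of 208 miRNAs compared, 22 were higher in the EV library, 62 were lower and 124 were neither. MiR-122-5p, a liver-abundant miRNA, had 160 reads in EVs and 1 in cells, a ratio of 1665 with a wide interval of 295 to 66172. MiR-5099 was 946-fold higher (772 to 1172), with 8545 reads against 94, and was the most abundant miRNA of the EV library at 14.7% of its miRNA reads. MiR-1949 was 114-fold higher (79.4 to 169), let-7k 31.8-fold (26.1 to 39.0), miR-125a-5p 15.2-fold (14.05 to 16.4) and miR-22-3p 8.39-fold (7.64 to 9.20). MiR-1198-5p, miR-690, miR-181a-5p and miR-15a-5p completed the 10 largest ratios, between 4.88-fold and 6.45-fold. MiR-181a-5p peaked at 19 nt in EVs (87.4% of its reads) and at 23 nt in cells. Counting only reads of 21 nt or more turned the log2 ratios of miR-181a-5p and miR-15a-5p to -0.75 each. Let-7k and miR-5099 had no reads of 21 nt or more in any library, so their ratios rest on shorter reads. Reads of 18 nt were 31.3% of miRNA reads of 18 nt or more in 4T1 EV, against 0.912% in 4T1 cells. For let-7k and miR-5099 a higher level in EVs therefore cannot be told apart from shorter EV reads.

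Among the miRNAs lower in 4T1 EVs, miR-30b-5p had 0 reads in EVs against 838 in cells, which makes it at least 26.8-fold lower. MiR-31-3p was at least 18.9-fold lower, miR-18a-5p at least 15.9-fold, miR-374b-5p at least 9.90-fold and miR-362-5p at least 9.45-fold, each with 0 reads in EVs. MiR-335-3p and miR-301a-5p also had 0 reads and were at least 3.43-fold and 3.30-fold lower. MiR-467a-5p, of the large Sfmbt2 cluster, had 3 reads against 3162, 101-fold lower (34.6 to 491). MiR-30c-2-3p had 1 read against 447, 43.0-fold lower with an interval of 7.67 to 1700.3, and miR-27a-5p had 6 against 1686 (log2 -4.64). MiR-21a-5p, a miRNA abundant in many tumours and the most abundant in 4T1 cells at 11.5% of miRNA reads, was 2.99-fold lower in EVs (2.87 to 3.12).

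By list, the miR-17-92 cluster and its paralogs, polycistrons associated with proliferation, were low in 4T1 EVs. Of 13 compared members 8 were lower and none was higher, with a median log2 ratio of -1.80 at percentile 1.65 of random lists. With reads of 21 nt or more the median was -1.09 and inside the range of random lists. MiR-20a-5p had 233 reads against 9020 (log2 -1.89), miR-17-5p 92 against 3021 (-1.65) and miR-93-5p 58 against 2791 (-2.20), and these were called lower. The group of miR-99, miR-100 and miR-125 had a median of -1.53 at percentile 0.56, but its members went both ways. MiR-100-5p (-1.54) and miR-99a-5p (-1.52) were lower, whereas miR-125b-5p (1.64) and miR-125a-5p (3.92) were higher. With 5 reads added, or with reads of 21 nt or more, this group no longer stood outside the central 95% of random lists. The other 11 lists with 3 or more compared members lay within that range. They included the let-7 family (median -0.72, 4 higher and 3 lower of 18, but 0.64 at percentile 99.5 with reads of 16 nt or more), the miR-23/27/24 clusters (-1.22, 2 higher and 5 lower of 7), the miR-15/16 family (-2.52, 1 higher and 4 lower of 6) and the Sfmbt2 cluster (-0.96, 1 higher and 6 lower of 30). The miR-30 family had a median of -0.45, with 3 of 10 lower. The cluster of miR-183, miR-96 and miR-182 was mixed, with miR-183-5p higher (1.78), miR-96-5p lower (-3.16) and miR-182-5p, which was also the median, at 0.21 and called neither, or at -2.35 with genome-aligned reads as the denominator. The miR-200 family had 2 lower of 6, with a median of -0.33. The ratios are relative to all miRNA reads. The median log2 ratio of the compared miRNAs was -1.06, TMM scaling moved it by 0.10 and median-of-ratios scaling by 0.14. With all genome-aligned reads as the denominator it moved by -2.55, and the share of higher among called miRNAs went from 26.2% to 2.73%. After thinning to the shallower library the median was -0.52, with 18 higher and 31 lower of 100, and with 5 reads added it was -0.39. The size of this median thus also depended on depth and on the reads added.

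The same comparison in 4TO7 gave 22 miRNAs higher in the EV library, 50 lower and 59 neither, of 131. MiR-122-5p had 1092 reads in EVs against 1 in cells, a ratio of 3752 (672 to 148348). MiR-5099 was 234-fold higher (164 to 345), let-7k 54.3-fold (36.2 to 84.9), miR-1949 53.3-fold (23.6 to 149) and miR-181a-5p 51.1-fold (33.5 to 81.7). The ratios of let-7k and miR-5099 again rest on reads shorter than 21 nt. The Hox-cluster miRNAs miR-10b-5p and miR-10a-5p had 66 and 62 reads in EVs against 6 each in cells, 37.8-fold (16.5 to 107) and 35.5-fold higher (15.4 to 100.5). The pair is near-identical in sequence and shares reads, as do miR-181b-5p and miR-181d-5p. MiR-128-3p was 7.46-fold higher, and miR-181b-5p and miR-181d-5p 5.70-fold and 5.43-fold. At the other end, miR-467a-5p had 1 read against 407, 118-fold lower (21.1 to 4690), miR-30b-5p 1 against 387, 113-fold lower (20.1 to 4460), and miR-31-3p 1 against 250, 72.8-fold lower (12.9 to 2885). MiR-374b-5p had 0 reads against 64 and was at least 6.21-fold lower. MiR-106b-5p, miR-32-5p, miR-365-3p, miR-30c-5p, miR-466f-3p and miR-19a-3p followed, between 13.4-fold and 32.6-fold lower. With all listed lengths and both strands counted, the log2 ratios of miR-374b-5p and miR-106b-5p turned positive, to 0.53 and 0.38.

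The let-7 family, whose members are associated with differentiation, stood high in 4TO7 EVs, with 6 of 14 compared members higher, 1 lower and a median log2 ratio of 0.80 at percentile 99.1. Let-7c-5p (1.57), let-7b-5p (1.43) and let-7e-5p (1.41) were higher, and let-7j (-1.16) was lower. With a minimum of 10 reads the family's median was -0.22, and with reads of 21 nt or more it was 0.15 and inside the range of random lists. The miR-10 family had a median of 1.71 at percentile 99.1, but its members split and none lay near that median. MiR-10a-5p (5.05) and miR-10b-5p (5.14) were higher, whereas miR-196a-5p (-1.74) and miR-196b-5p (-1.63) were below 0 and neither. With a minimum of 10 reads, or with reads of 16 nt or more, the miR-10 list no longer lay outside the central 95%. The miR-17-92 list was again low, with 8 of 11 members lower, none higher, a median of -2.50 and percentile 0.005. The remaining 7 lists with 3 or more compared members lay within the central 95%, among them the miR-29 family (-1.73, 2 of 3 lower, percentile 3.94, or 2.31 with 5 reads added), the Sfmbt2 cluster (-3.12, 8 of 8 lower, percentile 5.36, or 0.20 with reads of 16 nt or more and 2.05 with a minimum of 10 reads) and the group of miR-99, miR-100 and miR-125 (-0.23, 2 higher and 2 lower of 7, but 0.31 with median-of-ratios scaling). MiR-21a-5p was 7.71-fold lower in EVs (7.18 to 8.28) and miR-9-5p 5.51-fold lower (4.57 to 6.71). The median over all compared miRNAs was -0.96, and TMM moved it by 0.31, median-of-ratios scaling by 0.54 and genome-aligned reads by -0.66. After thinning to the shallower library it was -0.72, with 21 higher and 36 lower of 93, and with 5 reads added it was -0.89. The share of higher among called miRNAs was 30.6%, against 49.2% with median-of-ratios scaling and 16.05% with genome-aligned reads.

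Across the 129 miRNAs compared in both lines, the EV/cell log2 ratios had a Pearson r of 0.83 and a Spearman rho of 0.77, a correlation across miRNAs, which are not independent replicates. Of these, 13 were higher in EVs in both lines, where independent lists of the same sizes would share 2.90. The 13 were let-7b-5p, let-7c-5p, let-7k, miR-22-3p, miR-98-5p, miR-122-5p, miR-125a-5p, miR-125b-5p, miR-148a-3p, miR-181a-5p, miR-690, miR-1949 and miR-5099. A further 35 were lower in both, against 17.9 for independent lists, and included miR-16-5p, miR-19a-3p, miR-19b-3p, miR-20a-5p, miR-21a-5p, miR-27a-3p, miR-30b-5p, miR-31-3p, miR-93-5p, miR-103-3p, miR-106b-5p and miR-221-3p. Both sets hold members that share reads, such as let-7b-5p and let-7c-5p, or miR-669a-3p and miR-669o-3p, which had equal counts. The 2.90 and 17.9 treat members as independent, so the excess over them cannot be taken at face value. This overlap was not recomputed with collapsed paralogs. No miRNA was called higher in one line and lower in the other. The EV/cell ratio itself differed between the lines by more than 2-fold beyond counting error for 23 miRNAs. It was higher in 4T1 for 7 of them, including miR-5099, miR-24-3p, miR-125a-5p and miR-21a-5p. It was lower in 4T1 for 16, including miR-10a-5p, miR-10b-5p, miR-181a-5p, miR-181b-5p, miR-423-3p, miR-423-5p and miR-26a-5p. The higher side depended on the denominator. With genome-aligned reads every log2 difference moved by -1.90, none of the 7 was still called, and 4 of them were below 0, namely miR-24-3p (-0.0704), miR-125a-5p (-0.24), miR-21a-5p (-0.54) and miR-183-5p (-0.77). The 16 on the lower side were still called, among 66 in all. Median-of-ratios scaling left 4 of the 7 and all 16. Of the 13 miRNAs higher in EVs in both lines, genome-aligned reads left 5 called and reads of 21 nt or more left 7 of the 9 that could be compared. Let-7k and miR-5099 had no reads of 21 nt or more in any library, miR-690 and, in 4TO7, miR-181a-5p had fewer than 50, and miR-125b-5p and miR-98-5p were no longer called. Of the 35 lower in both, all could be compared at that length and 17 were still called. All 35 stayed below 0 in both lines, with medians of -1.61 in 4T1 and -2.49 in 4TO7. For miR-21a-5p, the genome cluster labelled mir-21 (mm9, chromosome 11, 86397618 to 86397668) gave log2 EV/cell ratios of -6.65 in 4T1 and -3.99 in 4TO7 per genome-aligned read, or -5.65 and -2.99 per covered nt, since it covered 25 nt in EVs and 50 nt in cells. The miRNA table gave -4.10 and -3.56 with that denominator, so both were lower in 4T1.

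**Figure D2:**
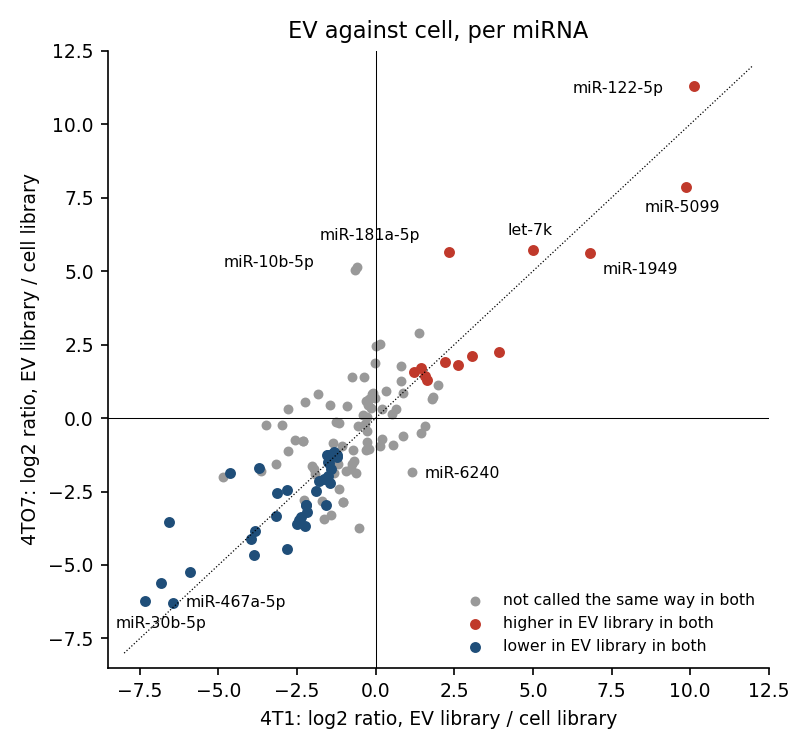
Log2 ratio of EV over cell library in 4T1 (x axis) against 4TO7 (y axis), 1 point for each of 129 miRNAs, with 1 library per group; the dotted line marks equal ratios. Points rest on 0.5 added reads where a library has 0 reads. The 13 miRNAs higher in both lie at the upper right and the 35 lower in both at the lower left, while miR-10b-5p is high in 4TO7 alone.

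The comparison of cells asked how the miRNA content of 4T1 differed from that of 4TO7. Of 208 miRNAs, 28 were higher in 4T1 cells, 11 were lower and 169 were neither. The largest differences were in the miR-200 family, which represses the transcription factors Zeb1 and Zeb2 and is a marker of epithelial cells. MiR-200c-3p had 1202 reads in 4T1 cells and 0 in 4TO7 cells, at least 118-fold higher, and miR-200a-3p had 1146 and 0, at least 113-fold higher. MiR-429-3p (333 reads), miR-141-3p (215) and miR-200a-5p (159) were also at 0 in 4TO7 cells, which gives at least 32.7-fold, 21.1-fold and 15.6-fold. MiR-200b-3p had 1026 reads against 1, a ratio of 302 (54.1 to 11947). All 6 compared members were higher, with a median log2 ratio of 7.64, or 5.92 with members at 0 set to their bound, and no random list reached that median.

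MiR-10b-5p and miR-10a-5p were 160-fold (73.4 to 436) and 154-fold (70.9 to 421) higher in 4T1 cells, with 3260 and 3147 reads against 6 each. The miR-10 family as a list had a median of 3.49 at percentile 99.6, which lay between its pairs and near no member. MiR-196b-5p (log2 -0.20, 235 against 79 reads) and miR-196a-5p (-0.18, 223 against 74) were neither higher nor lower. MiR-206-3p, known from skeletal muscle, had 154 reads against 0, at least 15.1-fold higher, but its log2 ratio was 1.58 and no longer past the limit with reads of 16 nt or more, and -0.0366 with all lengths. MiR-146a-5p, a feedback regulator of NF-kB signalling, was 20.1-fold higher (8.52 to 62.3). The inflammation list had a median of 1.37 at percentile 98.6, with miR-146a-5p and miR-155-5p higher (4.56-fold, 3.07 to 7.07) and both miR-21a arms neither; with a minimum of 10 reads its median was 0.57 and inside the range of random lists. MiR-34a-5p, a p53 target, was 15.2-fold higher (5.86 to 56.5). In the miR-30 family 3 of 10 members were higher, with miR-30a-5p at 2.39-fold and miR-30d-5p at 2.42-fold, but the median of 0.35 lay within the range of random lists.

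Lower in 4T1 cells were miR-210-3p, a hypoxia-induced miRNA, at 14.2-fold (9.38 to 22.04), and miR-152-3p at 13.0-fold (8.03 to 21.8). MiR-542-3p, miR-466f-3p, miR-450a-5p, miR-6240, miR-322-5p and miR-872-5p were 3.05-fold to 5.48-fold lower. MiR-221-5p and miR-221-3p, associated with basal and mesenchymal breast cells, were 2.64-fold and 2.27-fold lower. The list of miR-221 and miR-222 had a median of -1.18 at percentile 1.34, but 2 of its 3 compared members are these arms. The third, miR-222-3p (150 against 28 reads), had a larger share of miRNA reads in 4T1 cells and was neither. The let-7 family lay slightly lower, at a median of -0.35 and percentile 0.935, with only let-7b-5p of 18 members called. With all genome-aligned reads as the denominator both of these medians turned positive, to 0.32 and 1.15, and with a minimum of 10 reads let-7 moved inside the range of random lists. That denominator moved all log2 ratios by 1.503 and the share of higher among called miRNAs from 71.8% to 98.5%. The most abundant miRNA, miR-21a-5p, took 11.5% of miRNA reads in 4T1 cells and 11.8% in 4TO7 cells. Per genome-aligned read it was higher in 4T1 cells, with a log2 ratio of 1.46 in the miRNA table and 1.52 for the mir-21 genome cluster. The cluster of miR-183, miR-96 and miR-182 (median -0.091), the miR-17-92 list (-0.24) and the miR-29 family (-0.63) had no called member, and the miR-15/16 family (-0.65) had 1 lower of 6, miR-322-5p. With genome-aligned reads these 4 medians were also above 0, at 1.41, 1.26, 0.88 and 0.85. Of 30 Sfmbt2 cluster members 3 were higher and 1 lower, with a median of 0.78 at percentile 94.985. The list lay outside the central 95% with a minimum of 10 reads (0.79 over 53 members, percentile 100) and with 5 reads added (0.58, percentile 98.0), as did the miR-15/16 family with a minimum of 10 reads (-0.61, percentile 1.90).

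Between the EV libraries, 82 miRNAs were compared, and 20 were higher in 4T1 EV, 14 lower and 48 neither. The miR-200 family showed the same side as in cells. MiR-200b-3p had 162 reads in 4T1 EV and 0 in 4TO7 EV, at least 48.2-fold higher, and miR-200c-3p 108 and 0, at least 32.1-fold higher. MiR-200a-3p had 74 and 2, a ratio of 33.0 (8.82 to 278). The 3 compared members had a median log2 of 7.597, or 5.005 with their bounds, at percentile 99.3. MiR-206-3p had 56 reads and 0, at least 16.6-fold higher, although with reads of 16 nt or more its log2 ratio was -0.0746. MiR-146a-5p was 21.7-fold higher (7.14 to 108). MiR-10a-5p and miR-10b-5p were 2.76-fold and 2.80-fold higher, less than in cells, with log2 differences of -5.70 and -5.73 between the comparisons (counting intervals -6.88 to -4.51 and -6.91 to -4.55). The 3 compared members of the miR-30 family were higher, with a median of 1.65 at percentile 98.4, led by miR-30e-5p at 6.44-fold (4.53 to 9.40). With a minimum of 10 reads, or with reads of 21 nt or more, that list lay inside the range of random lists. MiR-24-3p, miR-5099 and miR-1949 were 3.78-fold, 3.61-fold and 3.37-fold higher, and miR-1981-5p 4.30-fold. MiR-21a-5p was 2.51-fold higher in the miRNA table, whereas per genome-aligned read the mir-21 genome cluster gave a log2 ratio of -1.13, against 0.93 from the miRNA table.

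MiR-122-5p was 7.65-fold lower in 4T1 EV than in 4TO7 EV (6.48 to 9.09). MiR-423-3p, miR-26a-5p, miR-99b-3p, miR-674-3p and let-7e-5p were 4.06-fold to 5.76-fold lower, and miR-125b-1-3p, let-7d-5p, miR-423-5p and miR-181a-5p 2.68-fold to 3.14-fold. With reads of 16 nt or more let-7e-5p (log2 -0.61) and let-7d-5p (-1.12) were no longer past the limit, and with TMM scaling neither were miR-423-5p and miR-181a-5p. The let-7 family had a median of -0.95 at percentile 1.965, with 5 of 11 members lower and none higher. Together, its members took 26.5% of miRNA alignments in 4T1 EV and 52.3% in 4TO7 EV, which includes reads listed under several members. With reads of 16 nt or more these shares were 58.0% and 60.1%, the median was -0.0094 at percentile 23.6, and none of the 11 members was called, so the lower let-7 level of 4T1 EV depended on the minimum length. With the same reads the group of miR-99, miR-100 and miR-125 had a median of -1.31 at percentile 1.11. The miR-23/27/24 clusters had 3 of 6 members higher and a median of 0.98 at percentile 95.6. The median over the 82 miRNAs was 0.14, TMM moved it by 0.17, median-of-ratios scaling by -0.10 and genome-aligned reads by -0.40. With the last, 37.9% of called miRNAs were higher, against 58.8%.

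**Figure D3:**
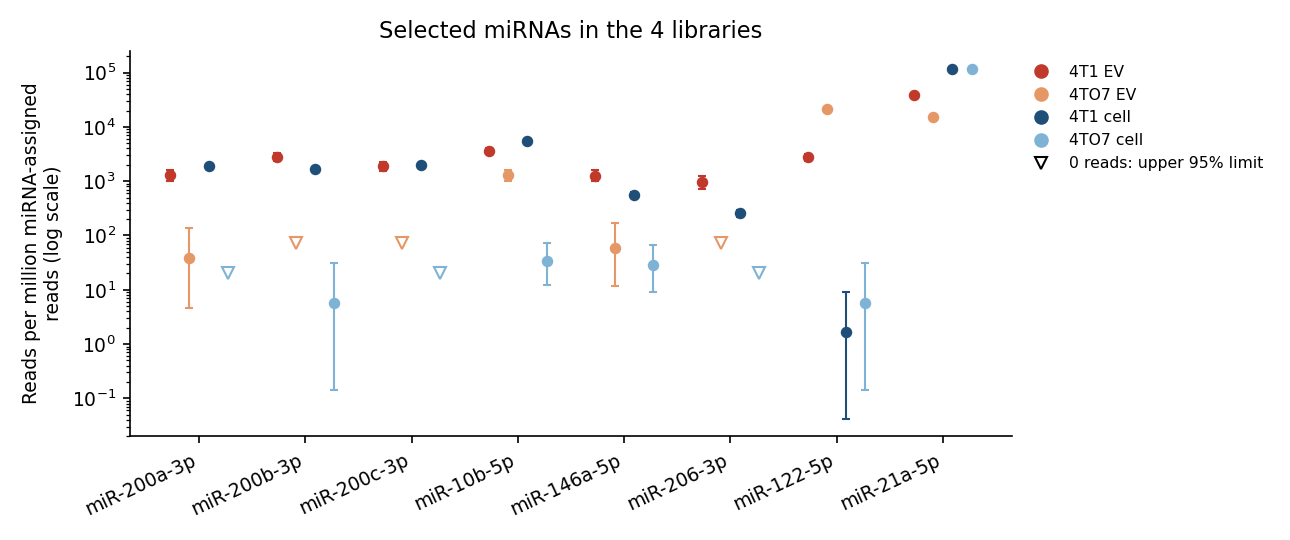
Levels of 8 miRNAs as RPM of miRNA-assigned reads on a log scale, 1 point per library with its exact Poisson 95% interval; open triangles give the upper limit where a library had 0 reads. The miR-200 members and miR-206-3p are seen in both 4T1 libraries, and miR-122-5p lies at 2760.4 and 21123 in EVs against 1.66 and 5.63 in cells.

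Markers of other cell types were rare among reads of 18 nt or more, with exceptions. The blood and serum list had 180 reads in 4T1 EV and 1136 in 4TO7 EV, nearly all miR-122-5p, against 9 and 4 in the cells. Members of the imprinted Dlk1-Dio3 cluster had 27 and 69 reads in EVs and 1 and 4 in cells, and none reached 50 reads. The mesenchymal and fibroblast list had 26, 24, 17 and 46 reads in 4T1 EV, 4TO7 EV, 4T1 cells and 4TO7 cells. The embryonic stem cell clusters had 0 reads of 18 nt or more, which allows each member up to 51.8 RPM in 4T1 EV, 58.0 in 4TO7 EV, 4.97 in 4T1 cells and 16.9 in 4TO7 cells. Muscle markers other than miR-206-3p had 8 reads in 4T1 EV and 16 in 4TO7 EV. With reads of 16 nt or more the whole muscle list had 980 and 703 reads in EVs, 0.810% and 0.962% of miRNA alignments, against 176 in 4T1 cells and 32 in 4TO7 cells. Of these miR-1a-3p had 471 and 357 in EVs, of which 98.7% and 99.2% were 16 nt long. The blood and serum list then had 809 and 2725 reads in EVs and 16 in each cell library. The neural list consisted almost wholly of miR-9-5p, with 8193 reads in 4T1 cells, 2178 in 4TO7 cells, 111 in 4T1 EV and 115 in 4TO7 EV. Of the epithelial list, miR-203-3p had 227 reads in 4T1 cells and 24 in 4TO7 cells, and miR-205-5p 0 and 41. Of the list of miR-34 and miR-449, miR-34a-5p had 207 and 4 reads and miR-449a-5p 6 and 18.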

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

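The tests of explanations in this part were all chosen after the results were seen, as were the minimum lengths and the scalings other than TMM, while the difference in EV/cell ratio was planned. For 9 miRNAs the EV/cell log2 ratio lay on opposite sides of 0 in the lines, with each counting interval excluding equality and a difference beyond 2-fold; whether it exceeds the spread between replicate cultures was not tested. The ratio was lower in 4T1 than in 4TO7 for miR-10b-5p (difference -5.73), miR-10a-5p (-5.70), miR-125b-1-3p (-2.79), miR-423-3p (-2.65), miR-92a-3p (-2.16), let-7e-5p (-1.80) and miR-26a-5p (-1.31), and higher for miR-6240 (2.99) and miR-24-3p (1.83). The opposite sides depended on the settings. With TMM or median-of-ratios scaling 8 of the 9 kept them, and miR-24-3p was above 0 in both lines. With genome-aligned reads as the denominator 5 of 9 kept them, since miR-26a-5p, miR-125b-1-3p, miR-24-3p and miR-6240 were then below 0 in both lines, and the difference of miR-24-3p was -0.0704. With reads of 16 nt or more let-7e-5p was above 0 in both lines (1.24 and 1.62), and with reads of 21 nt or more miR-26a-5p was above 0 (0.22 and 0.98) and miR-6240 below 0 (-2.68 and -4.02) in both. MiR-10a-5p, miR-10b-5p and miR-423-3p kept opposite sides under these 5 settings. MiR-92a-3p did too, but with reads of 21 nt or more its ratio in 4TO7 was 0.0796 and the difference -0.87, under 2-fold.

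The miR-10 pair was 35.5-fold and 37.8-fold higher in the 4TO7 EV library than in 4TO7 cells. If reads of the 4T1 cell library had been assigned to the 4TO7 EV library, 1.97% of them would be needed, and 80.9 miR-200 family reads should have come along; 4 were seen, with an upper bound of 10.2. If 4T1 EV reads had been the source, 124.97 would be expected, so the tables argue against both. Serum in the medium stays open as a source. At the ratio of miR-10b-5p to miR-122-5p in 4TO7 EV, the 4T1 EV library would need 9.67 miR-10b-5p reads, and it had 207, which decides nothing, and selective release by 4TO7 cells was not tested.

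MiR-122-5p was seen in EVs of both lines and hardly in cells. Serum miRNAs carried into the EV preparations may contribute, although the medium was made with serum cleared of EVs. The 6 other detected blood and serum markers summed to 20 reads in 4T1 EV against 8 in cells, 26.02-fold higher, and to 44 against 3 in 4TO7, 50.4-fold higher. The smaller of the lower bounds was 10.98, and the most abundant were miR-486-5p (14 and 31 reads in EVs) and miR-451a (2 and 9). A rise in EVs was not particular to these markers, since the Dlk1-Dio3 list was 281-fold higher in 4T1 (27 reads against 1) and 59.3-fold in 4TO7 (69 against 4). Whether the Dlk1-Dio3 reads also came from serum was not tested, so that list does not weigh against serum. Transfer of 4TO7 EV reads to 4T1 EV would need 14.7% of them and so 52043 reads at the largest cluster listed in 4TO7 EV and not in 4T1 EV, which the tables argue against. Release from the cells was not tested, and miR-122-5p reads per read of the other markers differed between the EV libraries, at 8 in 4T1 and 24.8 in 4TO7, or 23.5 and 39.1 with reads of 16 nt or more.

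The 35 miRNAs lower in EVs in both lines had median log2 ratios of -2.24 in 4T1 and -2.94 in 4TO7. Trimming of their EV reads to between 10 and 17 nt is argued against as the whole cause for 28 of them, which were still called in both lines when EV reads were counted from 10 nt against cell reads and totals from 18 nt (18 of the 35 with all reads and totals from 10 nt); the EV reads of the 35 rose from 9651 to 11924 in 4T1 and from 6845 to 7406 in 4TO7, and their medians became -1.89 and -2.56. For the other 7, among them miR-103-3p, miR-106b-5p and miR-221-3p, trimming cannot be told apart from a lower level, since their EV reads rose from 2306 to 4237 and from 2044 to 2398 but only miR-106b-5p in 4T1 came above 0 (0.87). Whether lower depth of the EV libraries contributed could not be decided by thinning the cell libraries, after which 30 were still called in both lines. Thinning leaves the expected share of each miRNA unchanged, so it could lose calls through wider intervals but not reveal a depth effect. Median-of-ratios scaling, which moved all ratios by 0.14 in 4T1 and 0.54 in 4TO7, left 22 called. A few abundant EV miRNAs taking reads from the rest could not account for these 22 through a shift of that size. For the other 13 such a shift cannot be told apart from a lower level. All 13 stayed below 0 but were no longer past the limit in both lines. Their medians went from -1.51 to -1.37 in 4T1 and from -1.53 to -0.99 in 4TO7. The EV compartment itself stays an open and untested explanation.

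Antisense alignments of 18 nt or more, which entered no comparison, numbered 1807 in 4T1 EV, 567 in 4TO7 EV, 4206 in 4T1 cells and 1367 in 4TO7 cells. Most were 20 nt reads opposite miR-3074-5p (1559, 328, 3778 and 996), and sense reads of 20 nt at miR-24-3p, whose precursor lies on the opposite strand, numbered 1560, 328, 3784 and 996. Alignments below 18 nt, also unused, were 76.0% of those listed in 4T1 EV, 49.01% in 4TO7 EV, 69.9% in 4T1 cells and 78.8% in 4TO7 cells.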

How the results depend on the processing

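Minimum lengths other than 18 nt, all lengths with both strands, collapsed paralogs and larger clusters were chosen after seeing the data, as were scalings other than TMM for the EV/cell difference and all settings for the miRNAs shared by both lines, and the other alternatives were planned. The 80 calls of the 10 largest and 10 smallest ratios per comparison were recomputed where a miRNA could still be compared, and 824 of 881 recomputed calls were the same, 45 were no longer past the limit and 12 changed sign. The 43 list medians were recomputed with TMM scaling, a minimum of 10 reads and 5 reads added, and 118 of 129 stayed on their side of the limit. TMM moves all ratios of a comparison alike, so its 43 could not change sides. With a minimum of 10 reads 35 of 43 stayed, and with 5 reads added 40 of 43 stayed. With minimum lengths of 16 and 21 nt 74 of 83 did. The 3 scalings changed the sign of 10 of 129, of which 8 were with genome-aligned reads. Some settings move none of these calls by construction, and their results in the 824 test nothing. They are 5 reads added (80), the minimums of 10 reads (80) and 200 reads (48), and summed arms (10, all of names without an arm). Median-of-ratios scaling and the denominator without the most abundant miRNAs could move calls and kept all 80, as did thinning all 67 that could be compared. TMM kept 78 of 80, genome-aligned reads 66, a minimum of 16 nt 72, all lengths with both strands 55 and a minimum of 21 nt 55 of 62. Reads summed over loci could not be run, since the tables list mature names and not loci. The EV/cell ratios pair the libraries by line, but no paired test across the 2 lines was run. Replicates could not be paired because the labels give no replicate numbers and each group has 1 library. Depth limits which miRNAs could be compared, since 75 and 70 reached 50 reads in the EV libraries against 206 and 121 in cells. Except where stated, the cause of a difference was not tested.

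With genome-aligned reads as the denominator, 5 miRNAs were higher and 178 lower in 4T1 EV against cells (22 and 62 in the main comparison), 13 were higher and 68 lower in 4TO7 EV against cells (22 and 50), 134 were higher and 2 lower in 4T1 against 4TO7 cells (28 and 11), and 11 were higher and 18 lower in 4T1 against 4TO7 EVs (20 and 14). The log2 ratios of miR-181a-5p (-0.22) and miR-15a-5p (-0.26) in 4T1 EV against cells and of miR-221-5p (0.10) and miR-221-3p (0.32) between cells changed sign. For the EV/cell difference 0 were higher and 66 lower in 4T1 (7 and 16), 5 of the 9 on opposite sides of 0 stayed so, and 5 of the 13 miRNAs higher in EVs in both lines were still called. Median-of-ratios scaling gave 30 higher and 31 lower in 4TO7 EV against cells, and 4 higher in 4T1 for the EV/cell difference. A minimum of 10 reads tests more miRNAs and gave 35 and 37 higher in EVs of 4T1 and 4TO7, and 22 lower in 4T1 in both line comparisons; the let-7 median in 4TO7 EV against cells became -0.22. A minimum of 200 reads tests fewer and left 5 lower between cells and 13 higher between EVs; for the difference in EV/cell ratio it left 8 lower in 4T1 (16) with a Pearson r of 0.89. Thinning left 31 lower in 4T1 EV against cells. With 5 reads added, 1 list in place of 2 lay outside the central 95% there.

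A minimum of 16 nt gave 111 lower in 4T1 EV against cells and 8 higher between EVs, with miR-206-3p at -0.0746 and the let-7 median in 4T1 EV against cells at 0.64 (from -0.72). A minimum of 21 nt gave 34 lower in 4T1 EV against cells, 6 lower between EVs and 6 lower in 4T1 for the EV/cell difference, with miR-181a-5p at -0.75 and miR-15a-5p at -0.75. It left 0 lists in place of 2 outside the central 95% in 4T1 EV against cells, 1 in place of 3 in 4TO7 and 1 in place of 3 between EVs; in the last 2 comparisons 1 list each (miR-10, miR-200) had only 2 members left and got no percentile. It left called 7 of the 13 miRNAs higher in EVs in both lines, of which 9 could be compared, and 17 of the 35 lower. All lengths and both strands bring 1908 listed names in place of 645. The numbers higher and lower were then 133 and 580 in 4T1 EV against cells, 102 and 360 in 4TO7, 156 and 17 between cells, and 70 and 22 between EVs. MiR-15a-5p (-5.98) in 4T1 EV against cells, miR-374b-5p (0.53) and miR-106b-5p (0.38) in 4TO7 EV against cells, and miR-206-3p between cells (-0.0366) and between EVs (-0.62) changed sign. Of the 35 miRNAs lower in EVs in both lines 17 were still called, or 18 with a minimum of 10 nt and the sense strand alone, and 22 with median-of-ratios scaling. Collapsing paralogs, which removes miRNAs, left 27 lower in 4TO7 EV against cells, 18 higher between cells, 7 higher between EVs and 3 higher in 4T1 for the EV/cell difference.

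Over all processed reads, the shares of reads of 18 nt or more aligned to mature miRNAs were 0.450% in 4T1 EV, 0.458% in 4TO7 EV, 2.68% in 4T1 cells and 0.893% in 4TO7 cells. Reads of 21 to 23 nt were 18.03%, 20.9%, 17.3% and 13.7% in that order. The lead of EVs over cells at 20 to 24 nt was thus much smaller in the narrower window for 4T1, and less so for 4TO7. Clusters of 10000 or more alignments numbered 165, 140, 420 and 319, and a minimum of 10 removed none.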

Other observations

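All values in this part were chosen after the data were seen. The lengths of reads assigned to miRNAs differed between compartments. Whether the short EV reads came from these miRNAs or from fragments of other RNAs was not tested. Reads past the annotated 3' end could not align and are missing from these shares. Among reads of 16 nt or more that started at the first or second base of the mature sequence, the median share that reached 21 nt was 45.7% over 82 miRNAs in 4T1 EV and 55.9% over 78 in 4TO7 EV, against 94.3% over 207 in 4T1 cells and 95.1% over 124 in 4TO7 cells. The share was lower in EVs for 63 of 78 miRNAs measured in both 4T1 libraries and for 51 of 64 in 4TO7. MiR-125b-5p had 14.2% (13.3% to 15.1%) in 4T1 EV and 17.5% in 4TO7 EV, against 95.4% and 94.7% in cells, and its most common length was 18 nt in EVs and 22 nt in cells. Let-7a-5p peaked at 16 nt in 4T1 EV and at 22 nt in the other libraries. MiR-182-5p peaked at 25 nt in both cell libraries, at 18 nt in 4T1 EV and at 19 nt in 4TO7 EV.

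MiR-21 differed between the genome and the miRNA tables. The cluster that the authors labelled mir-21 (mm9, chromosome 11, 86397618 to 86397668) held 600815 alignments in 4T1 cells and 174386 in 4TO7 cells, against 71102 and 21507 sense alignments listed for miR-21a-5p at any length. The ratio was 8.45 in 4T1 cells, 8.11 in 4TO7 cells, 6.01 in 4TO7 EV and 1.44 in 4T1 EV, and the longest listed miR-21a-5p read was 22 nt. Per genome-aligned read, the log2 ratio of 4T1 EV over 4TO7 EV was -1.13 from the cluster and 0.93 from the mature table, so the direction for miR-21 between EVs depended on the table. In 4T1 EV against cells the same log2 ratios were -6.65 and -4.10, where the cluster covered 25 nt in EVs and 50 nt in cells, which gives -5.65 per covered nt.

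A cluster on chromosome 1 (mm9, 173033191 to 173033241) held 355194 alignments in 4TO7 EV, 6.87% of its genome-aligned reads. It held 0.302% in 4T1 cells and was not listed in 4T1 EV or in 4TO7 cells. MiR-122-5p was mostly 17 nt long in EVs, at 77.7% of its reads of 16 nt or more in 4T1 and 58.1% in 4TO7. Of the 684 clusters listed in 4T1 EV, 45.5% overlapped a cluster of 4TO7 EV and 38.6% a cluster of 4T1 cells.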
